A study of Mus musculus with 24 samples.

How the data were processed

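RNA was measured in the cerebellum and hippocampus of 12 mice, 4 in each of 3 groups, as 24 libraries in 6 groups. Per the labels' protocols, total RNA was extracted with a lipid tissue kit and DNase, reverse transcribed, amplified with the Ion AmpliSeq Transcriptome Mouse panel, which reads a short amplicon for each gene, and sequenced on an Ion S5. Per the submitters' processing notes, reads were checked with FastQC 0.11.9, trimmed with Trimmomatic 0.39, aligned with STAR 2.7.9a to GRCm39 and counted with featureCounts 2.0.3, and per the file headers the annotation was GENCODE M34 and counting ignored strand. The deposited values are raw read counts per gene for 57126 genes, with no normalization by the authors. Reads of a gene and an overlapping antisense gene cannot be told apart in unstranded counts, and the amplicons were not located here. PCR reads without molecular identifiers are not independent molecules, so counting intervals and floors cover counting error only.

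Samples were grouped by the labels' genotype, treatment and tissue. Gene symbols were matched by gene ID for 51884 of 57126 IDs, and IDs with a count and no symbol held 0.21% of all counts. Coordinates are those of the deposited files. Pairs of replicates differed by far more than sampling noise (chi-square per degree of freedom of 6.99 to 46.2), so every library counted as its own replicate. Library totals ran from 1833609 to 11590081 counts, median 7.98 M.

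Each tissue was fitted with edgeR 4.0.16 (R 4.3.3) using TMM factors, filterByExpr over the 3 groups, robust dispersions and the quasi-likelihood test, with sex as a covariate and all 12 libraries in the fit. Sex was estimated from the Npc1-/- mice, since the Npc1+/+ mice were all female, so a fitted fold can differ from the ratio of the group means. The adjusted p is Benjamini-Hochberg over the genes tested, with 0.05 as the threshold. Differences between tissues were tested over 24 libraries with the animal as block and a tissue by sex term. The pairing comes from the animal numbers in the labels, and the values bear it out only weakly. Deviations of the cerebellar and hippocampal libraries of a mouse correlated from -0.40 to 0.452, above 0.1 in 7 of 12 mice. In 2 of 12 mice the cerebellar library correlated best with its own hippocampal library. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. There were 33 gene lists, of which 1, of sex-linked genes, only checked the labels, and 1, of blood and leukocytes, had too few measured members for the list test. CPM are counts scaled to the TMM-adjusted library size.

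The groups, designs, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule named Npc1, then for each tissue the 10 highest and 10 lowest log2 fold changes among genes past the adjusted p with a mean of at least 5 CPM and groups that did not overlap, leaving out Xist, Y-linked genes and clone names. Where fewer than 10 genes passed it named the 5 with the smallest p as values. For each gene list it named up to 4 members past the adjusted p, or up to 2 as values where none passed, and for the tissue difference the 10 with the smallest p. Some genes that the rule named are not reported here.

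The tests were tried on simulated counts with genes changed 1.5-fold, 2-fold and 4-fold, drawn from the real means and library sizes. Each comparison had a single simulated data set, with 67, 67 and 66 genes changed at these folds. For the genotype comparison 6.0%, 47.8% and 95.5% of changed genes were recovered in cerebellum and 3.0%, 26.9% and 86.4% in hippocampus, with 9 and 10 false calls among 12782 and 12624 genes. For the tissue difference in genotype 3.0%, 6.0% and 68.2% were recovered with 5 false calls among 13300 genes.

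The alternatives, 88 planned, were no sex covariate, a replicate block, DESeq2 1.42.0, limma-voom, RLE factors, library totals, no filter, a stricter filter, only the groups compared, female mice only, each library left out in turn, and other list tests. A further 23 were chosen after seeing the data: a choroid plexus score or a GC slope as covariate, and fits without libraries in doubt. The GC content of a gene was that of its longest transcript in GENCODE vM21, matched by gene ID for 99.7% of the tested hippocampal genes. Age and the range of ion codes go wholly with genotype, and no fit could adjust for them. No median fold over all genes shifted by more than 0.1 (log2) between scalings. Markers of cortex and dentate gyrus, the list tests between tissues and the GC check were also chosen after seeing the data. Each group of 4 libraries was checked for a library apart from the rest in its total, Npc1, its scores of choroid plexus, myelin, GC and region markers, and the CPM of the highest and lowest named genes of the genotype comparison.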

Results

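Niemann-Pick disease type C1 follows from loss of NPC1, a lysosomal membrane protein that exports cholesterol. The data were gene-level read counts from the cerebellum and the hippocampus of 12 mice of the BALB/cNctr-Npc1m1N/J strain, in which the Npc1-/- genotype models the disease. There were 4 Npc1+/+ mice given vehicle, 4 Npc1-/- mice given vehicle and 4 Npc1-/- mice given dipyridamole, an inhibitor of nucleoside transport and of cyclic nucleotide phosphodiesterases. Dipyridamole was injected at 30 mg/kg on 5 days per week from postnatal day 28 until the brains were taken. Each mouse gave both tissues, for 24 libraries, and the library totals ran from 1833609 to 11590081 counts, with a median of 7.98 M. The shallowest library was the cerebellum of Npc1-/- vehicle replicate 2, and the hippocampus of the same mouse held 3.84 M counts. The 4 Npc1+/+ mice were all female and 65 days old, while the 8 Npc1-/- mice were of both sexes and 63 days old, so sex entered each fit and age could not be separated from genotype.

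Npc1 itself was checked first, because the genotype sets its level. Npc1 (ENSMUSG00000024413.15, GRCm39 chromosome 18, 12322749 to 12369457, minus strand) stood at 107 ± 4.94 CPM in Npc1+/+ cerebellum and at 30.3 ± 7.68 CPM in Npc1-/- vehicle cerebellum (mean ± SD, n = 4). In hippocampus the values were 74.98 ± 14.9 CPM and 19.0 ± 2.38 CPM (n = 4). Every Npc1-/- library, dipyridamole included, lay below every Npc1+/+ library of its tissue, the highest being 39.3 CPM and the lowest Npc1+/+ value 60.5 CPM. Xist and the Y-linked genes matched the labelled sex in all 24 libraries.

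**Figure D1:**
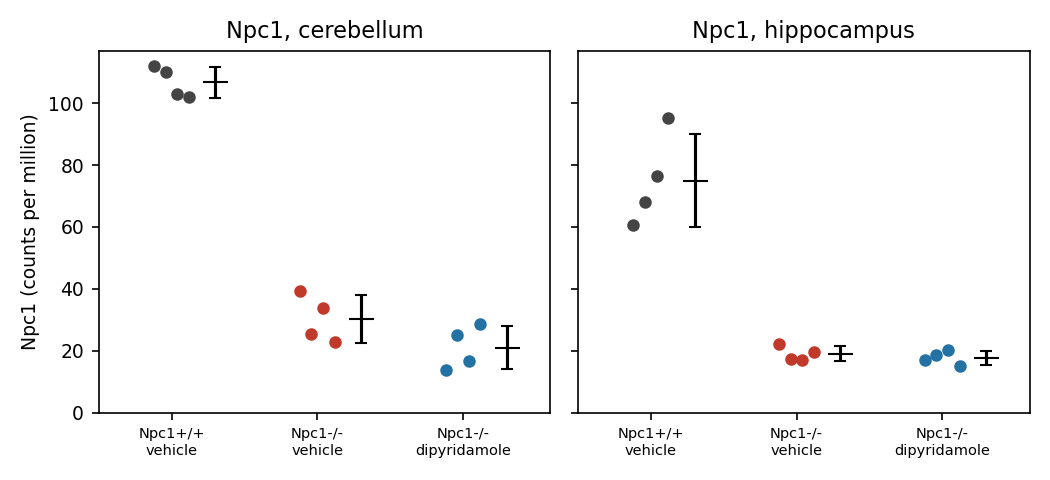
Npc1 in CPM, counts scaled to library size (vertical axis, linear from 0) for each library of the 3 groups (horizontal axis) in cerebellum (left) and hippocampus (right). Points are libraries, and the bar beside them gives the mean and SD of 4 libraries. The Npc1-/- libraries reached at most 39.3 CPM, and the Npc1+/+ libraries lay at 60.5 CPM or above.

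The first comparison asked what the loss of Npc1 changed in the cerebellum. Genes of activated microglia rose most and genes of Purkinje cells, the output neurons of the cerebellar cortex, fell most. Of the disease-associated microglia list, 18 of 20 measured members rose (20 when adjusted over the list alone), with a median log2 fold change of 3.52. Of the Purkinje cell list, 26 of 28 members fell (26 adjusted over the list alone), with a median of -2.22 (log2). Lyz2 (ENSMUSG00000069516.9, GRCm39 chromosome 10, 117113236 to 117118226, minus strand), the lysozyme of myeloid cells, went from 18.2 ± 2.48 to 514 ± 90.4 CPM, and Calb1 (ENSMUSG00000028222.3, chromosome 4, 15881264 to 15908064, plus strand), the calcium buffer calbindin, from 694 ± 35.3 to 54.9 ± 19.8 CPM (mean ± SD, n = 4). In all, 1286 of 12921 tested genes passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, 764 higher and 522 lower in Npc1-/- vehicle mice, and 759 of them changed at least 2-fold.

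The 10 highest named genes in the cerebellum were mostly of myeloid cells and lysosomes. Itgax, an integrin of activated microglia, rose by a log2 fold change of 7.64 ± 0.47 (SE) on 4 counts in the Npc1+/+ libraries combined, and Gpnmb, a glycoprotein of lipid-laden phagocytes, by 7.54 ± 0.38. Atp6v0d2, a subunit of the vacuolar proton pump, had 3 counts in the Npc1+/+ libraries combined, and its ratio of counts was 128 with a counting interval of 43.2 to 623. Clec7a (5.71 ± 0.26), Hpse (5.50 ± 0.29), C3ar1 (4.89 ± 0.30), Cd180 (4.53 ± 0.39), C3 (4.23 ± 0.29) and Hvcn1 (3.94 ± 0.32) followed. At the other end stood Fgf7 (-4.41 ± 0.33), Car8 (-4.07 ± 0.27), Slc5a1 (-3.68 ± 0.65), Itpka (-3.50 ± 0.24), Ppp1r17 (-3.41 ± 0.28), Ryr1 (-3.14 ± 0.43), Pcp2 (-3.10 ± 0.34), Atp2a3 (-3.05 ± 0.31) and Arhgef33 (-2.94 ± 0.33). Itpka, Ryr1 and Atp2a3 act in calcium signalling and calcium release or uptake. Each of these genes had groups that did not overlap and an adjusted p by edgeR of 0.00107 or less.

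Other groups of the innate immune response moved with the microglial genes in the cerebellum. Of the complement list, 7 of 8 members rose (8 adjusted over the list alone), among them C4b at 3.34 ± 0.24 (log2, SE) and Itgb2 at 3.15 ± 0.27. Of the interferon response list 12 of 21 rose (13 adjusted over the list alone), among them Cxcl10 at 4.47 ± 0.72, Lgals3bp at 2.45 ± 0.17 and Oasl2 at 2.23 ± 0.26. Homeostatic microglial genes rose in 7 of 12 cases (8 higher and 1 lower adjusted over the list alone), with Cx3cr1 at 1.80 ± 0.22. Of the antigen presentation list 5 of 12 rose (5 adjusted over the list alone), with B2m at 1.54 ± 0.17 and H2-K1 at 1.37 ± 0.17. Its list test gave an adjusted p of 0.0612 with an estimated correlation. Gfap, the intermediate filament of astrocytes, rose by 3.78 ± 0.18 and Cd44 by 2.86 ± 0.23, as 10 of 15 members of the reactive astrocyte list did (13 adjusted over the list alone).

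Lysosomal genes rose in 15 of 35 cases in the cerebellum (16 adjusted over the list alone), with Ctss at 2.41 ± 0.22 (log2, SE), Ctsd at 1.92 ± 0.20 and Grn at 1.45 ± 0.15. Of the cholesterol synthesis list 5 of 22 members rose (6 adjusted over the list alone), among them Hsd17b7 at 1.06 ± 0.20 and Fdft1 at 0.77 ± 0.20, in log2. The list's adjusted p was 0.00736, and the adjusted p was 0.257 with an estimated correlation. Of the LXR target list 6 of 14 rose (6 higher and 1 lower adjusted over the list alone), with the lipoprotein genes Apoe at 1.69 ± 0.17 and Apoc1 at 2.00 ± 0.35. The list's adjusted p was 0.0103, and the adjusted p was 0.28 with an estimated correlation. The metallothionein Mt1 (1.51 ± 0.17) and the heme oxygenase Hmox1 (2.17 ± 0.28) were the 2 of 16 oxidative stress genes that rose (2 higher and 1 lower adjusted over the list alone). The list had an adjusted p of 0.0693 with an estimated correlation.

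Among the lists that fell in the cerebellum, Bergmann glia, the radial astrocytes around Purkinje cells, had 5 of 10 members lower (9 adjusted over the list alone), with Etv5 at -1.47 ± 0.20 and the glutamate transporter gene Slc1a3 at -0.91 ± 0.16 (log2, SE). Slc1a6, at -2.16 ± 0.23, is also in the Purkinje list. Synaptic protein genes fell in 7 of 28 cases (12 adjusted over the list alone), with Shank1 at -1.24 ± 0.19 and Dlg4 at -0.93 ± 0.25. Of the immediate early genes 8 of 23 fell (10 lower and 1 higher adjusted over the list alone), with Nr4a3 at -2.71 ± 0.39 and Nr4a1 at -2.10 ± 0.30. The list test gave an adjusted p of 0.0807 with an estimated correlation. In the unfolded protein and heat shock list 6 of 18 fell and 1 rose (9 and 2 adjusted over the list alone). The chaperone genes Sdf2l1 (-1.60 ± 0.25), Manf (-1.29 ± 0.20) and Hspa5 (-0.97 ± 0.17) fell while the stress transcription factor Atf3 rose (2.79 ± 0.31), and the list had an adjusted p of 0.152 with an estimated correlation. Myelin genes fell in 3 of 23 cases (7 adjusted over the list alone), Ugt8a by a log2 of -1.23 ± 0.26, with an adjusted p of 0.359 with an estimated correlation. Oxidative phosphorylation genes fell in 2 of 27 cases, with 1 higher (2 and 1 adjusted over the list alone; adjusted p of 0.157 with an estimated correlation).

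The other 12 lists tested in the cerebellum did not pass the list test. Of granule cell genes 1 of 16 fell, Gabra6 at -0.89 ± 0.22 (log2, SE), and of interneuron genes 3 of 14 fell and 1 rose, with Eomes at -2.06 ± 0.36 and Pvalb at -1.19 ± 0.25. Astrocyte genes went both ways, with 3 of 12 higher and 2 lower (Aqp4 1.36 ± 0.30, Slc1a3 -0.91 ± 0.16). The sphingolipid list had 2 of 25 members lower, the list of precursors and newly formed oligodendrocytes 1 of 15 lower, the autophagy list 1 of 18 higher, the adenosine list 1 of 19 higher (Entpd2, 1.07 ± 0.18) and the phosphodiesterase list 1 of 17 higher and 1 lower (Pde1b 0.78 ± 0.20, Pde5a -1.73 ± 0.21). No member of the endothelial, mural and meningeal, or choroid plexus lists passed. Of the markers of neighbouring brain regions, Th (1.69 ± 0.35) and Chat (1.15 ± 0.34) were higher, 2 of 14 (3 adjusted over the list alone). Too few members of the blood and leukocyte list were measured for a list test, and Alas2, of red blood cells, fell (-1.70 ± 0.50).

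The list tests used camera with a preset correlation of 0.01. With it 17 of the 29 lists tested in the cerebellum passed, and 9 did with an estimated correlation: the lysosomal, both microglial, complement, interferon, reactive astrocyte, Bergmann glia, Purkinje and synaptic lists. The count of called genes was 474 without Npc1-/- vehicle replicate 3, the only female mouse of its group, 421 with only the groups compared in the fit, and 2249 without the sex covariate. The slope of expression on transcript GC content was lower in the 4 Npc1+/+ cerebellar libraries (-0.114 to -0.048 log2 per 10 percentage points) than in the 4 Npc1-/- vehicle libraries (-0.022 to 0.132). With that slope as a covariate, chosen after seeing the data, 2314 genes passed, 1224 of the 1286 among them.

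**Figure D2:**
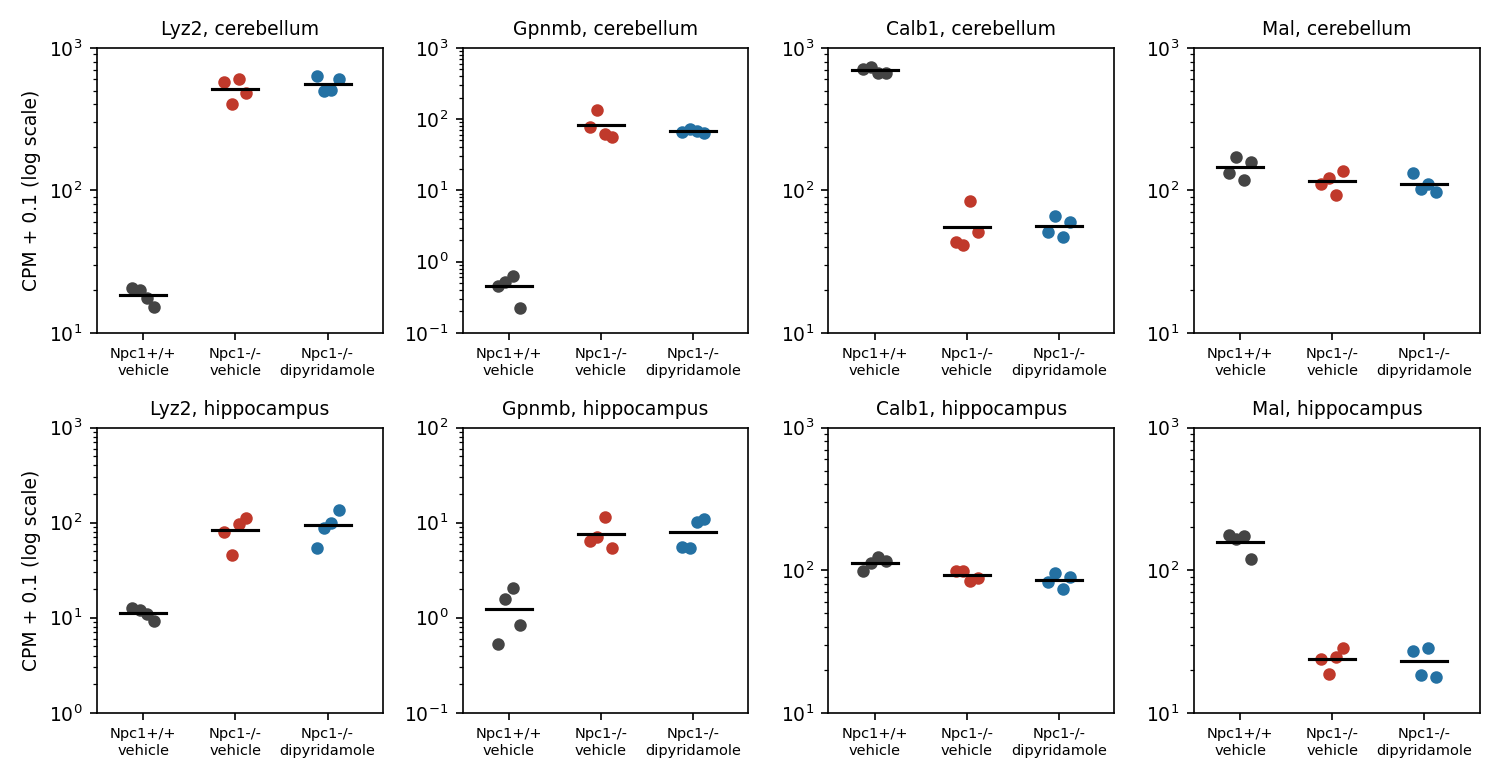
CPM plus 0.1 on a log axis for Lyz2, Gpnmb, Calb1 and Mal (columns) in cerebellum (top) and hippocampus (bottom), by group. Points are libraries and the line is the mean of 4. Lyz2 rose in both tissues (log2 fold changes of 4.89 and 3.30), Calb1 fell by 3.44 (log2) in cerebellum and had -0.40 in hippocampus, which did not pass, and Mal fell by 2.71 (log2) in hippocampus.

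In the hippocampus the myelin list had the largest median change of the lists tested (-2.37, log2). The disease-associated microglial list had the smallest adjusted p of the list test with an estimated correlation (5.54e-06). Next to myelin in median came the choroid plexus list (-2.31, with 1 of 14 members above 0 and none past the adjusted p). That fitted fall was not visible in the libraries, whose choroid plexus scores ran from 1.63 to 5.91 in Npc1+/+ and from 2.5 to 5.68 in Npc1-/- vehicle mice. It depended on the sex covariate: without it the members Sostdc1 and Calml4 went from -4.27 to -0.64 and from -2.25 to -0.58. Genes of mature oligodendrocytes and myelin fell, 19 of 23 members (23 adjusted over the list alone), and the list passed with an estimated correlation (adjusted p 0.00121). Mal (ENSMUSG00000027375.15, GRCm39 chromosome 2, 127475146 to 127498615, minus strand), a myelin membrane protein, went from 158 ± 26.7 to 23.8 ± 4.03 CPM and Opalin from 101 ± 8.64 to 15.3 ± 5.12 CPM (mean ± SD, n = 4). Activated microglial genes rose as well, 13 of 21 members of the disease-associated list (15 adjusted over the list alone) with a median of 2.04 (log2). In all, 206 of 12740 genes passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, 130 higher and 76 lower, and 170 changed at least 2-fold.

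The lowest named hippocampal genes were mostly members of the myelin list, and Nipal4 (-2.94 ± 0.48, log2 and SE) was among them though not in that list. They included the gap junction gene Gjb1 (-2.76 ± 0.51), the myelin glycoproteins Mog (-2.98 ± 0.37) and Mag (-2.81 ± 0.36), Ugt8a (-2.77 ± 0.28), Mal (-2.71 ± 0.27), Aspa (-2.60 ± 0.42) and Opalin (-2.53 ± 0.48). The 10 highest were Itgax (4.58 ± 0.46), Clec7a (4.12 ± 0.47), Lyz2 (3.30 ± 0.31), C3 (2.95 ± 0.69), C3ar1 (2.94 ± 0.23), C4b (2.91 ± 0.21), Ifit1 (2.51 ± 0.36), Hvcn1 (2.37 ± 0.45), Hpse (2.28 ± 0.32) and Oasl2 (2.27 ± 0.35). Their adjusted p by edgeR was 0.0494 or less.

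Complement genes rose in 6 of 8 cases in the hippocampus (7 adjusted over the list alone), with C1qc at 1.82 ± 0.28 (log2, SE). Interferon response genes rose in 8 of 21 (12 adjusted over the list alone), with the regulator Irf7 at 2.12 ± 0.28 and the chemokine Cxcl10 at 5.46 ± 0.72. Antigen presentation genes rose in 4 of 11 (6 adjusted over the list alone), with H2-D1 at 1.73 ± 0.20, and reactive astrocyte genes in 4 of 16 (7 adjusted over the list alone), with Gfap at 1.80 ± 0.19 and Osmr at 2.08 ± 0.25. Lysosomal genes rose in 5 of 35 cases (11 higher and 1 lower adjusted over the list alone), with Grn at 1.01 ± 0.17. Atp6v0d2 was among them, with 2 counts in the Npc1+/+ libraries combined and a ratio of counts of 48.1 with a counting interval of 12.9 to 405. Apoe, at 0.94 ± 0.15, was the only LXR target of 14 that passed. None of 21 cholesterol synthesis genes passed, and the list's median was -0.16 (log2; adjusted p 0.0623). Of the precursor and newly formed oligodendrocyte list 4 of 15 fell (5 adjusted over the list alone), with Bcas1 at -1.92 ± 0.34, Enpp6 at -1.68 ± 0.34 and Sox10 at -1.23 ± 0.19. The list had an adjusted p of 0.0597 with an estimated correlation.

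No member of the principal neuron (20 measured), GABAergic interneuron (13) or synaptic protein (29) lists passed in the hippocampus, nor any of the adenosine, phosphodiesterase, autophagy, oxidative phosphorylation, endothelial, mural and meningeal, choroid plexus, neighbouring region and homeostatic microglia lists; adjusted over the list alone, 2 phosphodiesterase and 2 homeostatic genes were higher. Calb1, part of the principal neuron list, had a log2 fold change of -0.40 ± 0.16. The homeostatic list passed with the preset correlation and had an adjusted p of 0.0667 with an estimated correlation. The astrocyte list (Aldoc 0.80 ± 0.18, 1 of 11 higher; 0.0597), the sphingolipid list (Ugt8a, 1 of 25 lower; 0.0736), the immediate early list (Arc -1.48 ± 0.32 and Dusp6 -1.07 ± 0.25, 2 of 27 lower; 0.261) and the unfolded protein list (Sdf2l1 -1.23 ± 0.17 and Hspa5 -0.77 ± 0.16 lower, Atf3 1.69 ± 0.39 higher; 0.0736) did likewise, each number being the adjusted p with an estimated correlation. Of the oxidative stress list 1 of 16 rose, Mt1 at 0.79 ± 0.17. Choroid plexus transcripts differed widely between hippocampal libraries, with Ttr from 22.7 to 2560 CPM in Npc1+/+, 61.8 to 7240 CPM in Npc1-/- vehicle and 27.7 to 4400 CPM in dipyridamole-treated mice.

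The count of 206 rested on few libraries. It was 31 without Npc1-/- vehicle replicate 3, 102 without Npc1+/+ replicate 3, 118 without Npc1+/+ replicate 2, 51 with female mice only, of which 1 was an Npc1-/- vehicle mouse, and 419 by DESeq2. It was 177 without the hippocampal libraries in doubt (Npc1-/- vehicle replicate 2 and dipyridamole replicate 4), a setting chosen after seeing the data. Of the 35 ways to split these 8 mice into groups of 4, another split called 721 genes, none of which was among the 206.

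The same mice gave both tissues, so the difference of the genotype effect between tissues was tested within animals. It passed for 155 of 13436 genes by edgeR's quasi-likelihood test, 82 with the higher log2 fold change in hippocampus and 73 with the lower. Members of the Purkinje list were among the genes with the smallest p. The hippocampal minus cerebellar difference was 3.10 ± 0.26 (log2, SE) for Calb1, 4.03 ± 0.46 for Car8, 2.05 ± 0.26 for Rgs8 and 2.06 ± 0.27 for Icmt. Itpka (3.67 ± 0.41), Tuba8 (2.49 ± 0.27), Cep76 (2.62 ± 0.35) and Gcnt1 (2.57 ± 0.34) differed in the same direction, and Gpnmb (-4.06 ± 0.45) rose further in cerebellum (7.54 against 3.35). Tested between tissues in a step chosen after seeing the data, 10 of 25 shared lists passed with the preset correlation and 2 with an estimated one: myelin, with 14 of 23 members lower in hippocampus and a median difference of -2.10 (adjusted p 0.0134), and disease-associated microglia, with 5 of 21 lower and a median of -1.01 (adjusted p 0.00076). The count was 27 without Npc1-/- vehicle replicate 3, 90 without Npc1+/+ replicate 3 and 386 without the tissue by sex term.

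Among the 12336 genes tested in both tissues, 113 were higher in Npc1-/- vehicle mice in both, against 7.3 by chance for independent lists, and 18 were lower in both, against 2.9. No gene was called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes of the tissues correlated with r = 0.537. The tissues came from the same mice, which the chance values leave out, and how much of the overlap comes from shared animals was not measured.

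**Figure D3:**
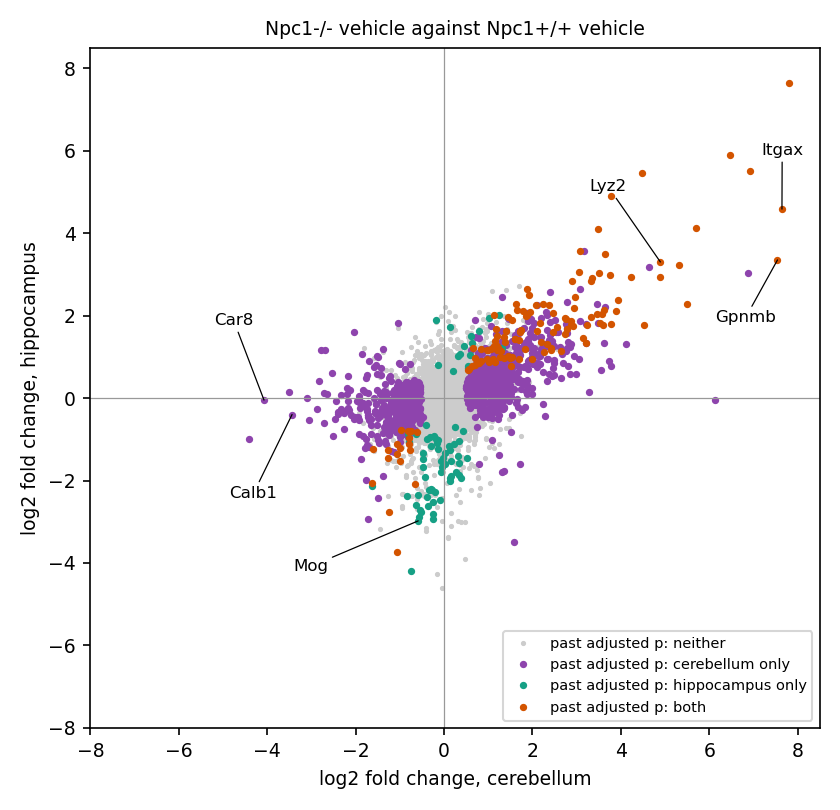
Log2 fold change of Npc1-/- vehicle against Npc1+/+ vehicle mice in cerebellum (horizontal axis) and hippocampus (vertical axis), 1 point per gene tested in both tissues, coloured by the tissue in which it passed the adjusted p. Gpnmb, Itgax and Lyz2 lie high in both tissues, Calb1 (-3.44 and -0.40) and Car8 (-4.07 and -0.05) lie left of the centre, and Mog lies low in hippocampus.

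The next comparison asked what dipyridamole changed in Npc1-/- mice. No gene passed in either tissue by edgeR's quasi-likelihood test, and none did by DESeq2 or limma-voom. At an unadjusted p under 0.05 edgeR gave 300 of 12921 genes in cerebellum and 93 of 12740 in hippocampus. DESeq2 gave 313 and 102, and limma-voom 499 and 320. Each count is below a share of 0.05 of the genes, the share expected with no drug effect, so there was no excess of small p. The groups did not overlap at 1.21% of genes in cerebellum and 1.19% in hippocampus, against 2.86% by chance. The test may be conservative here. In cerebellum the smallest p belonged to Bhlha9 (-1.10 ± 0.27, log2 and SE), Crym (-0.97 ± 0.25), Arpc3 (-1.02 ± 0.28), Osbpl5, an oxysterol-binding protein gene (-0.84 ± 0.23), and the small GTPase gene Rab18 (-0.53 ± 0.14), all with an adjusted p of 1 by edgeR. In hippocampus it belonged to Slfn3 (1.18 ± 0.29), Ttc26 (-0.70 ± 0.21), Rhog (-1.30 ± 0.40), Clec11a (0.79 ± 0.25) and Ice2 (0.70 ± 0.23), likewise with an adjusted p of 1. In cerebellum, testing all genes with no filter on low counts called 13 genes (3 higher and 10 lower in dipyridamole-treated mice), 9 of which were in the filtered set, and under the other settings tried none passed. On counts simulated from the real gene means, library sizes and fitted dispersions the test recovered 20.9% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 97.0% of those changed 4-fold in cerebellum, and 4.5%, 55.2% and 92.4% in hippocampus. Whether real libraries vary as little as such counts was not tested directly. Counts redrawn from the fitted folds and dispersions called more genotype genes than the real libraries did. Their mean was 2346 in cerebellum and 664 in hippocampus, against 1286 and 206 observed, so the recovered shares may be too high.

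No member of any gene list passed between dipyridamole and vehicle in either tissue, whether adjusted over all genes or over the list alone. The dipyridamole medians were 0.05 (log2) for Purkinje genes and -0.05 for disease-associated microglial genes in cerebellum. In hippocampus the disease-associated microglial median was 0.02 and the mean -0.02. Of the lists nearest to the drug's known targets, the adenosine list had medians of 0.06 in cerebellum and -0.12 in hippocampus, the phosphodiesterase list -0.03 and -0.02, and the immediate early and CREB target list -0.12 in cerebellum and -0.002 in hippocampus, where the mean was 0.02. The smallest p in these lists belonged to Dpp4 (0.50 ± 0.26), Pde8a (-0.25 ± 0.18) and Per1 (-0.38 ± 0.18) in cerebellum. In hippocampus the list test passed for myelin (median -0.22, Fa2h -0.53 ± 0.30) and choroid plexus (median -0.48), with an adjusted p of 0.000128 and 0.0209 at the preset correlation and an adjusted p of 0.908 for each with an estimated correlation. The hippocampal library of dipyridamole replicate 4 stood apart, with the dentate gyrus gene Prox1 at 14.2 CPM against 88.7 to 134 CPM in the other 11 libraries and the cortical gene Cux2 at 134 CPM against 21.2 to 44.7 CPM, and without it and Npc1-/- vehicle replicate 2, a setting chosen after seeing the data, no gene passed. For a difference between tissues in the dipyridamole fold, none of 13436 genes passed by edgeR's quasi-likelihood test or by DESeq2, with 222 and 169 genes at an unadjusted p under 0.05. On simulated counts that edgeR test recovered 1.5% of genes changed 1.5-fold, 34.3% of those changed 2-fold and 72.7% of those changed 4-fold, so smaller differences could be missed.

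**Figure D4:**
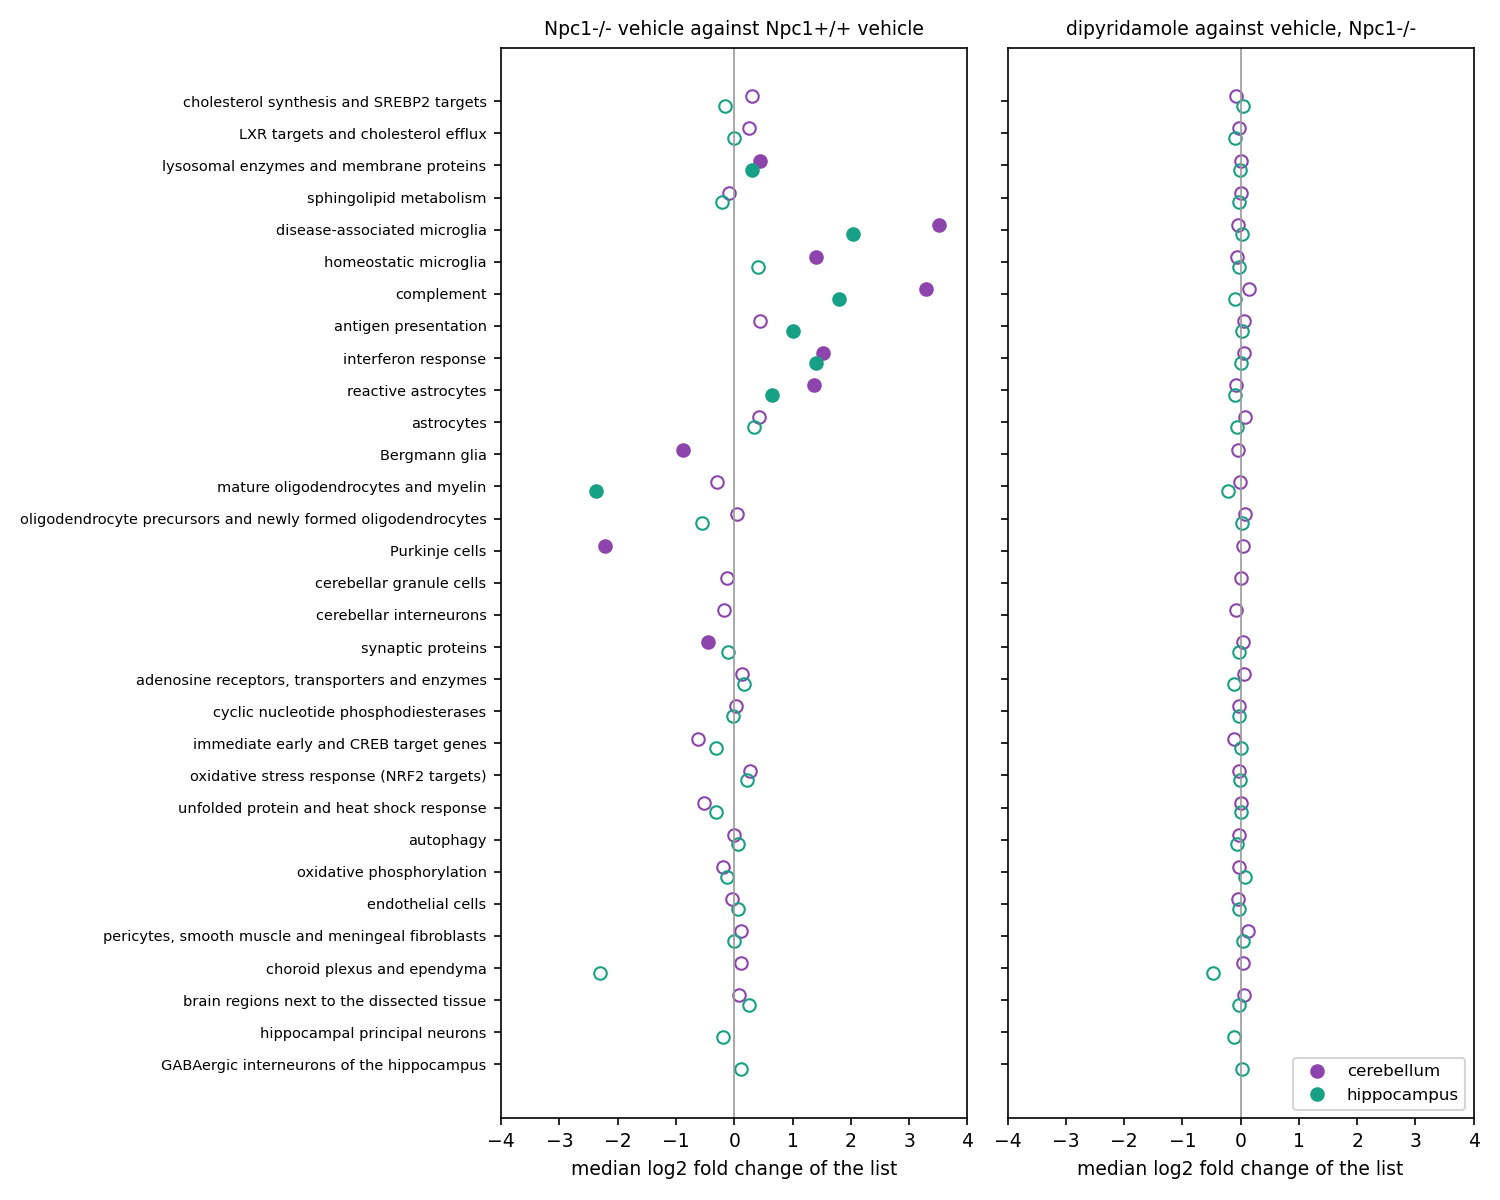
Median log2 fold change of each gene list (horizontal axis) for Npc1-/- vehicle against Npc1+/+ vehicle mice (left) and for dipyridamole against vehicle in Npc1-/- mice (right), in cerebellum (purple) and hippocampus (green). Filled points passed an adjusted p of 0.05 by camera with an estimated correlation. The disease-associated microglia list stood at 3.52 and 2.04 and the hippocampal myelin list at -2.37 on the left, while no list was filled on the right.

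Whether dipyridamole moved genotype-changed genes back toward Npc1+/+ levels was asked by the sign of the folds. Of the 1286 genes called in cerebellum, 67.5% had a dipyridamole fold opposite to the genotype fold, and of the 206 in hippocampus 59.7% did. Both folds use the same vehicle Npc1-/- libraries, and in 50 simulated data sets with no drug effect the share was 66.8 ± 0.82% (SD) in cerebellum and 72.5 ± 1.60% in hippocampus. The simulated shares were over more genes, a mean of 2346 in cerebellum and 664 in hippocampus, so they are not matched to the observed sets. The correlation across genes was -0.35 against -0.33 simulated in cerebellum and -0.09 against -0.48 in hippocampus, and the covariance -0.165 against -0.144 and -0.041 against -0.355. With the vehicle libraries divided so that the folds shared none, the share averaged 47.7% in cerebellum (27.3% to 56.0% over 6 divisions) and 38.9% in hippocampus (22.7% to 47.7%). The cerebellar share lay within the simulated range of 65.0% to 69.3%, and the hippocampal share lay below the simulated range of 67.9% to 76.9%.

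The last comparison asked what differed between dipyridamole-treated Npc1-/- mice and Npc1+/+ mice. In cerebellum 19 of 20 disease-associated microglial genes (20 adjusted over the list alone), 8 of 8 complement genes (8 adjusted over the list alone) and 16 of 35 lysosomal genes (17 adjusted over the list alone) were higher, and 26 of 28 Purkinje genes were lower (26 adjusted over the list alone). In hippocampus 22 of 23 myelin genes were lower (23 adjusted over the list alone), with a median of -2.71 (log2), and 13 of 21 disease-associated microglial genes were higher (16 higher and 1 lower adjusted over the list alone). Each of these lists passed with an estimated correlation. The hippocampal choroid plexus list had a larger fitted median, -3.01, with 0 of 14 members above 0 and none past the adjusted p. In the list test it passed at the preset correlation (adjusted p 0.00529) and had an adjusted p of 0.531 with an estimated one. Its scores overlapped, from 1.65 to 5.38 in dipyridamole-treated and from 1.63 to 5.91 in Npc1+/+ libraries, so the sex-adjusted median was not taken as a change. The dipyridamole-treated Npc1-/- mice differed at 1864 of 12921 genes in cerebellum (1051 higher, 813 lower) and at 342 of 12740 in hippocampus (203 higher, 139 lower) by edgeR's quasi-likelihood test. In cerebellum the count was 858 without dipyridamole replicate 4 and 1203 without replicate 3, the female mice of that group. In hippocampus it was 130 without dipyridamole replicate 4, 199 and 178 without Npc1+/+ replicates 2 and 3, and 144 without the libraries in doubt. These counts were not tested against those of the vehicle mice.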

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

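The myelin scores of female mice and the tests of white matter, of batch or age, of the dipyridamole library and of library size in the other split were chosen only after the result was seen, as were the between-tissue list tests and the settings with the GC slope or the choroid plexus score as covariate. Chance puts a library apart in about 1 in 20 groups of 4, and 8 of 116 groups tested had such a library.

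Myelin genes were lower in the hippocampus of Npc1-/- vehicle mice by a median log2 fold change of -2.37, and also by -2.37 with female mice only, a fit with 1 Npc1-/- vehicle library in which 8 of 23 members passed in place of 19. The tables still argue against sex, since the myelin score was 3.92 in female Npc1-/- hippocampal replicate 3 of the vehicle and of the dipyridamole group (3.12 in dipyridamole replicate 4, whose dissection is in doubt) and 5.91 to 6.23 in the 4 female Npc1+/+ libraries. They also argue against choroid plexus content (-2.20 with its score as covariate) and transcript GC content (-2.35 with the GC slope as covariate). The GC content of the amplicons themselves, which were not located, was not tested. Less white matter in the dissected tissue stays open, because the precursor list had a median of -0.56 with 4 of 15 members lower, and it cannot be told apart from a loss of myelin transcripts in Npc1-/- mice. Batch and age cannot be told apart from genotype, since 0 of the Npc1-/- libraries shared the ion code range or the age of the Npc1+/+ libraries.

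The hippocampal library of dipyridamole replicate 4 had a dentate marker score of 1.76, far below the other 3 of its group. Its depth, 7.47 M counts, lay inside the range of the other hippocampal libraries, which argues against low depth. Cortical markers were higher in it by a median log2 ratio of 1.48 (11 of 11 above the median of the other libraries) and dentate markers lower by a median of -3.09 (6 of 6), so cortex in place of part of the hippocampus is a candidate explanation. A mislabelled sample stays open, because Npc1 at 15 CPM and the sex-linked genes exclude a wrong genotype or sex and not another mouse of the same kind, and its label gives ion code 124, the same as that of the cerebellar library of its mouse. No biological explanation was tested.

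Of the 35 splits of the 8 hippocampal mice compared for genotype, 2 gave at least 206 genes, the real split included, so chance was not excluded for that count, and the highest other split gave 721. That split set Npc1-/- vehicle replicates 1 and 4 and Npc1+/+ replicates 2 and 4 against the remaining 4 mice, with 289 genes higher and 432 lower. Whether it reflects chance or a structure of the samples that the labels do not name was not decided. Library size is argued against, since the first side had the larger total in 7 of 16 pairs. Transcript GC content stays open: the correlation across genes, which are not independent replicates, was -0.131 (Spearman), and the median GC was 47.2% for genes called higher, 53.2% for those called lower and 49.8% for the rest. No biological explanation was tested.

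For the other genotype counts 1 of 35 splits, the real one, gave as many genes. These were the cerebellum (1286, highest other 671) and the tissue difference (155, highest other 47). Dipyridamole-treated against Npc1+/+ mice gave 1864 genes in cerebellum (highest other 0) and 342 in hippocampus (highest other 0). No count can do better than 1 of 35, and a split that mixes genotypes puts any genotype effect into the spread. The splits therefore cannot exclude chance for these counts. The cerebellar split that called 671 genes was the real split with Npc1-/- vehicle replicate 2 and Npc1+/+ replicate 1 exchanged. It thus kept much of the genotype contrast, and its genes were not examined further. For dipyridamole against vehicle the count was 0, which all 35 splits reach whatever the data, so the splits decide nothing there. The highest other split gave 41 genes in cerebellum, 12 in hippocampus and 2 in the tissue difference.

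Other libraries stood apart from the rest of their group of 4. Car8 was at 901 CPM in Npc1+/+ cerebellum replicate 3 and Ryr1 at 11.6 CPM in Npc1+/+ cerebellum replicate 4. C3ar1 was at 53.3 CPM in Npc1-/- vehicle cerebellum replicate 2, and the choroid plexus score was 2.29 in replicate 1 of that group. The total was 6.12 M counts in dipyridamole cerebellum replicate 2. Ugt8a was at 52.2 CPM in Npc1+/+ hippocampus replicate 4 and Nipal4 at 3.11 CPM in Npc1-/- vehicle hippocampus replicate 4.

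The genotype difference itself differed between tissues, by the interaction term, at 155 genes. The hippocampal minus cerebellar log2 difference was 3.10 for Calb1, 2.49 for Tuba8, -4.06 for Gpnmb, 4.03 for Car8, 3.67 for Itpka, 2.05 for Rgs8, 2.06 for Icmt, 2.62 for Cep76 and 2.57 for Gcnt1. Of gene lists, disease-associated microglia (median -1.01) and myelin (median -2.10) differed between tissues.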

How the results depend on the processing

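The fits with a GC slope, a choroid plexus score or without the libraries in doubt were chosen after seeing the data. Genotype in cerebellum called 1286 genes: 2249 without the sex covariate, 613 with the replicate block, 1973 by limma-voom, 421 with only the groups compared, 2314 with the GC slope, and 474 (without Npc1-/- vehicle replicate 3) to 1866 with a library left out. Genotype in hippocampus called 206: 490, 55, 433, 47 and 368 under the same 5 settings, 419 by DESeq2, 51 with females only, and 31 to 238 with a library left out. Dipyridamole-treated against Npc1+/+ mice gave 1864 genes in cerebellum: 1171 with the replicate block, 2863 by limma-voom, and 858 to 1803 with a library left out. In hippocampus it gave 342: 195 with the block, 689 by DESeq2, 560 by limma-voom, 179 with females only, 746 with the GC slope, 144 without the libraries in doubt, and 130 to 286 with a library left out. The tissue difference gave 155: 386 without the tissue by sex term and 27 to 227 with a library left out. Dipyridamole against vehicle gave 0 genes, except 13 in cerebellum with no filter (Alb, Htr5b, Hoxb8 and Tpi-rs4, outside the filtered set, and 9 others). The fits with females only have 1 Npc1-/- vehicle library, assumed to vary like the other groups. The cause was not tested for any of these.

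Gene lists past the adjusted p went, with an estimated correlation, from 17 to 9 (genotype, cerebellum), 18 to 11 (dipyridamole-treated against Npc1+/+, cerebellum), 13 to 7 and 16 to 8 (the same in hippocampus) and 2 to 0 (dipyridamole, hippocampus; also 0 by fry and 1 without Npc1-/- vehicle replicate 2). For dipyridamole in cerebellum, 0 lists became 1 without the sex covariate and 1 with the replicate block. The share of opposite signs fell from 67.5% to 47.7% and from 59.7% to 38.9% with the vehicle libraries divided, where the folds still shared the sex term.

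Whether replicate numbers pair the groups was not decided. The deviations of same-numbered libraries correlated above 0.1 in 0 to 2 of 4 pairs. In no pair of groups did every library correlate best with its own number. For the tissues of the same mouse, which the labels pair, the own library was the best match in only 2 of 12 mice. Such correlations therefore cannot exclude a pairing of the groups. Of 6110 values of named genes under alternatives, 5734 kept their direction and side of the threshold, 334 lost it, 29 gained it and 13 reversed, all of genes that had not passed or that passed no test: for dipyridamole in cerebellum Selplg (-0.06 with the GC slope), Alas2 (-0.234 to 0.68 with a library left out, below 0 without Npc1-/- vehicle replicates 3 and 4) and S100a9 (-0.73 with the replicate block, -0.13 by DESeq2, -0.918 to 0.593 with a library left out), for genotype in hippocampus Calml4 (0.074) and Sostdc1 (0.63) with the block, and for dipyridamole in hippocampus Fgfr3 (-0.283 to 0.023), Hspa1a (-0.518 to 0.033) and Dbh (-0.791 to 0.143) with a library left out, above 0 without Npc1-/- vehicle replicate 3. The 6110 values include genes named without passing, which count as kept while they still do not pass. The share that kept therefore does not measure how stable the passing genes were. Depth limits the cerebellum of Npc1-/- vehicle replicate 2 most, at 1.83 M counts.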

Other observations

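The genes named in this part were chosen after their values were seen, and all of its tests were chosen after the result was seen. In the cerebellum of Npc1-/- vehicle mice, Spi1 rose by a log2 fold change of 2.33 ± 0.28 (SE), Irf8 by 2.49 ± 0.31, Ptprc by 2.27 ± 0.31 and Laptm5 by 2.64 ± 0.18. Trh, the precursor of a releasing hormone, rose by 4.08 ± 0.84 from 0.499 CPM, and the non-coding H19 by 2.87 ± 0.36. In hippocampus, Adamts4 (-2.23 ± 0.36), Abca8a (-2.21 ± 0.44), Plxnb3 (-1.79 ± 0.38), Lpar1 (-1.52 ± 0.26) and Car2 (-1.46 ± 0.22) fell. No group of these genes was tested. The adjusted p of these genes by edgeR was 0.0283 or less.

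Th, which makes catecholamine precursors, rose in Npc1-/- vehicle cerebellum by 1.69 ± 0.35 (log2, SE), and Ddc by 1.66 ± 0.31. Of brain stem tissue in the dissection, a hypothesis, noradrenergic tissue is argued against, since the higher of the log2 fold changes of Dbh and Slc6a2 was 0.25. Other brain stem tissue stays open, since Chat, of cholinergic neurons, was higher as well (1.15 ± 0.34). Of the 13 genes called without the filter, Slc6a4 (-0.99), Rln3 (-1.35), Htr5b (-3.06) and Hoxb8 (-3.18) were lower in dipyridamole-treated than in vehicle Npc1-/- cerebellum, but the fixed list of neighbouring brain regions did not pass: its median was 0.06 (mean -0.04), with 9 of 14 members above 0 and an adjusted p of 0.796. For serotonergic tissue the test did not decide: across the 8 cerebellar Npc1-/- libraries Th and Tph2 had r = -0.87 (exact permutation p = 0.00791) and rho = -0.79 (exact p = 0.0279), two-sided, the only relation computed, and r was -0.20 without the 2 libraries farthest in Tph2, so the relation rests on those libraries.

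A larger number of microglia of unchanged state may raise all microglial genes alike. In cerebellum the median of the disease-associated list was 3.52 and that of the homeostatic list 1.40 (log2), a difference of 2.11 (permutation p = 0.00974 over genes, which are not independent replicates), which argues against more microglia of unchanged state as the whole cause. In hippocampus the difference was 1.64 (p = 0.0158 by permutation).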
